A study of Mus musculus with 12 samples.

How the data were processed

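Gene expression was measured by RNA sequencing of total RNA from mouse liver in 12 libraries, 3 in each of 4 groups. The groups were wild-type sham (Sham), wild type (WT), the RIPK1 D138N mutant (RIPK1_D138N) and a line labelled TNFR1/2 knockout (TNFR12_KO). Only the Sham group carries a sham label. The other 3 groups were taken as the ischemia arm from the title and design of the series. The time between operation and collection is not given in the sources used here. No sham libraries of the mutant genotypes were analysed here, so a difference at baseline and a different response to ischemia cannot be separated for either mutant. The labels do not say whether the repeats of a group are separate animals, and p-values therefore measure only the spread between these samples.

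The authors deposited FPKM values (fragments scaled to transcript length and sequencing depth) for every gene. Per the submitters' processing notes, the tools included STAR 2.5.4a, Cufflinks 2.2.1 and Cuffdiff, with the mm10 build. Per the file headers, 1 table holds the FPKM of all libraries. The columns of RIPK1_D138N and TNFR12_KO were matched to their replicate numbers, but those of WT and Sham only to their group, so WT and Sham libraries carry no number here. It lists 53796 genes, of which 53702 (99.8%) have an identifier in the GENCODE M21 annotation. That annotation supplied the coordinates, on the mouse build of its release. A symbol shared with an earlier row occurred 131 times, and the row with the highest mean was then used. No strand setting is given in the sources used here, and genes with near-identical copies, such as the Mup, Cyp2c, Cyp2a and Saa families and ribosomal protein pseudogenes, can share fragments.

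FPKM carries no count, but the low values fell on whole-number steps. Across the 66 pairs of libraries, 31.0 to 83.1% (median 64.7%) of the ratios of low values lay within 0.2% of a ratio of small whole numbers. A common scale matched 63 of the 66 pairs within 0.5%. It put the number of fragments behind 1 FPKM per kilobase of transcript at 34.8, 61.7 and 40.8 in WT, 25.9, 11.4 and 11.4 in Sham, 22.6, 24.5 and 18.8 in RIPK1_D138N, and 22.0, 31.0 and 33.7 in TNFR12_KO, from 570 genes. These figures combine depth with the authors' scaling. Low values are coarsest in 2 of the 3 Sham libraries.

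Zeros in the table can be failed estimates. Alb, Apoe and Serpina1b are listed at 0 in every library. A further 24 genes belong to loci listed at 0 in all libraries of a group while reaching at least 100 FPKM in another group, among them 11 in Sham, 10 in WT, 4 in RIPK1_D138N and 15 in TNFR12_KO. These genes stayed in the tests, as fixed beforehand, but none is named with a fold change. This exception was made after their values were seen.

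Each comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, in 1 model of 4 group means over the 12 libraries. The 11728 genes with at least 1 FPKM in at least 3 libraries were tested. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. Fold changes on this scale understate the change of low genes. Ratios are ratios of mean FPKM. Tested on simulated data for each comparison (11728 genes, 200 of them changed), the procedure recovered 69, 69, 68 and 73% of genes changed by 1 log2 unit in WT vs Sham, RIPK1_D138N vs WT, TNFR12_KO vs WT and RIPK1_D138N vs TNFR12_KO. For genes changed by 2 log2 units it recovered 98, 95, 99 and 98%. False calls made up 9.7, 4.7, 7.2 and 5% of the calls. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, and the noise was normal. Recovery of lower genes was therefore not tested.

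The 43 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. Members were also counted after adjustment over the list alone. The ischemia response score places each library on the wild-type difference, with 0 at Sham and 1 at WT. It held out each WT and Sham library from the choice of genes that scored it, used 5535 to 6204 genes, and was compared by exact permutation (two-sided), for which 3 against 3 libraries give a smallest p of 0.1. Overlap between the mutants was set beside 100 random regroupings that share the WT libraries, or the Sham libraries for comparisons with Sham. Each regrouping added shuffled deviations of the libraries from their group means to the overall mean of each gene, so no group differed. Counts of called genes in such data cannot show what shared libraries add where many genes differ. The Sham regroupings, and those for the shares of the WT vs Sham genes in the mutants, were added after the data were seen.

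Named genes followed a rule fixed beforehand. It admitted, per comparison, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, with a mean of at least 5 FPKM in the higher group and no predicted name. It also admitted up to 3 called members of each list with the smallest adjusted p, and the targeted genes. The genes printed from those admitted were selected after their values were seen. List members named because 5 or fewer were called in a direction are outside the rule and were also chosen after their values were seen. Alternatives covered a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, only the groups compared, a replicate block for RIPK1_D138N vs TNFR12_KO, array weights, a robust variance prior, and leaving out each library. Added after the data were seen were fits without RIPK1_D138N replicates 2 and 3, which hold Xist, and without the loci listed at 0. Some genes that the rule admits are not reported here.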

Results

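Liver RNA was profiled in 12 libraries from mice with or without ischemia, an interruption of blood supply. RIPK1 is a kinase that acts downstream of TNF receptors in cell death and inflammation, and D138N is a mutation known to remove its kinase activity. TNFR1 and TNFR2 are the receptors of the cytokine TNF. The FPKM of all genes summed to 721200, 649373 and 750501 in Sham, 291465, 303514 and 288934 in WT, 518580, 489348 and 502879 in RIPK1_D138N, and 509673, 512931 and 441296 in TNFR12_KO. Between 10135 and 10653 genes reached 1 FPKM in a library. Pearson correlations of log2 values across genes were 0.946 to 0.985 within groups and 0.800 to 0.959 between groups. RIPK1_D138N replicates 2 and 3 held Xist, the X-inactivation transcript, at 20.1 and 23.4 FPKM and the Y-linked Ddx3y at 0.0176 and 0 FPKM. The other 10 libraries held Xist at no more than 0.0824 FPKM and Ddx3y at 11.97 FPKM or more.

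The targeted genes were measured first. Tnfrsf1a (ENSMUSG00000030341, chromosome 6, 125349362 to 125362484), which encodes TNFR1, stood at 69.5 ± 16.5 FPKM in Sham, 35.1 ± 2.90 in WT, 19.8 ± 1.10 in RIPK1_D138N and 18.5 ± 3.28 in the libraries labelled TNFR1/2 knockout (mean ± SD, n = 3). Tnfrsf1b (ENSMUSG00000028599, chromosome 4, 145213463 to 145246870), which encodes TNFR2, stood at 6.92 ± 2.69, 9.51 ± 1.20, 5.52 ± 0.499 and 6.83 ± 2.70 FPKM in the same order. Transcripts of both receptors were thus still listed in the libraries labelled knockout, and a value per gene cannot show whether part of the gene is deleted. Tnfrsf1a was lower in TNFR12_KO than in WT (log2 fold change -0.90, SE 0.185, limma adjusted p = 0.00153) and lower in RIPK1_D138N than in WT (-0.80, SE 0.185, adjusted p = 0.00304). Ripk1 (ENSMUSG00000021408, chromosome 13, 34002363 to 34037147) stood at 3.88 ± 0.859 FPKM in WT, 3.48 ± 0.434 in RIPK1_D138N and 3.94 ± 0.290 in TNFR12_KO, and its level does not check a point mutation.

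The comparison of WT with Sham asks what ischemia changed in wild-type liver. Most tested immediate early genes, NF-κB targets and hypoxia genes rose, and most genes of secreted hepatocyte proteins and oxidative phosphorylation fell. Acute-phase genes fell in 16 of 25 cases and rose in 1 with the loci listed at 0 left out (median -1.318). Saa1, an acute-phase gene, read 19790 to 24270 FPKM in Sham and 3416 to 5334 in WT. Sham is thus not a baseline free of acute-phase transcripts. Ccl2, a monocyte chemokine, stood at 68.9 ± 5.14 FPKM in WT against 0.281 ± 0.242 in Sham (mean ± SD, n = 3), and Cd14, a co-receptor for bacterial lipopolysaccharide, at 185 ± 62.8 against 3.27 ± 0.702 (log2 fold change 5.41, SE 0.359, limma adjusted p = 2.05e-07). Nnmt, nicotinamide N-methyltransferase, fell from 1661 ± 290 FPKM in Sham to 8.14 ± 1.95 in WT (log2 fold change -7.51, SE 0.286, adjusted p = 2.17e-09). Bhmt and Mat1a, enzymes of methionine metabolism, fell by 5.17 and by 4.69 on the log2 scale.

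Of the immediate early genes, which answer stimuli without new protein synthesis, 19 of 20 rose, also when adjusted over the list alone, where 19 rose. Among them were Fos, at 36.9 ± 5.23 against 1.36 ± 0.381 FPKM, Atf3, at 131 ± 41.7 against 2.84 ± 0.716, and Maff, at 57.7 ± 7.07 against 1.40 ± 0.350. Of the NF-κB targets 16 of 19 rose, with Tnfaip3 at a log2 fold change of 2.77 and Relb at 2.38. Of the hypoxia genes 19 rose and 2 (Bnip3 and Ldha) fell among 24, with Ndrg1 at 3.38 and Ankrd37 at 3.08. Of the cytokines and chemokines 14 rose and 3 (Cxcl1, Cxcl9 and Cxcl13) fell among 21, and Cxcl10 stood at 32.3 ± 1.09 against 0.582 ± 0.0818 FPKM. Genes of matrix remodelling rose in 11 of 17 cases, among them Timp1, an inhibitor of matrix proteases, at 43.4 ± 10.4 against 0.394 ± 0.140 FPKM. Interferon-stimulated genes rose in 16 and fell in 6 of 29 cases, with Rsad2 at 4.07 and Ifit3 at 2.35. Camera called each of these lists higher (adjusted p from 4.79e-15 to 0.000273). With an estimated correlation the adjusted p was 0.049 for immediate early genes and 0.00156 for hypoxia, and 0.0803, 0.154, 0.0581 and 0.0963 for NF-κB targets, cytokines, matrix and interferon.

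All 26 tested genes of secreted hepatocyte proteins fell, with a median of -2.02 (1 of them is listed at 0 in a group), as did all 31 nuclear genes of oxidative phosphorylation (median -1.81). Across genes the fold change rose with transcript length (Spearman rho 0.309). That trend was removed only for the secreted list, so its share in the fall of oxidative phosphorylation genes was not tested. F9, coagulation factor IX, fell from 70.1 ± 5.89 to 11.1 ± 1.79 FPKM and Ndufs1, a complex I subunit, from 41.6 ± 2.06 to 11.2 ± 1.43. Complement and coagulation genes fell in 30 of 32 cases. Of the genes with periportal expression 19 fell and 1 (Cdh1) rose among 22, and of the pericentral ones 22 fell and 1 (Slc1a4) rose among 24. Otc, a urea cycle enzyme, fell from 158 ± 12 to 17.0 ± 4.33 FPKM, and Cyp3a11, a drug-metabolizing cytochrome, from 2220 ± 357 to 311 ± 34.6. Fatty acid oxidation genes fell in 24 of 29 cases and 1, Pdk4, rose. Among those that fell was Slc25a20, the mitochondrial carrier of acylcarnitines, which went from 124 ± 12.1 to 13.8 ± 0.814 FPKM. Camera called these lists lower (adjusted p from 8.17e-10 to 3.00e-05). None passed with an estimated correlation, where the adjusted p was 0.104 for secreted proteins, 0.233 for oxidative phosphorylation, 0.0915 for complement, 0.246 for both zones and 0.0803 for fatty acid oxidation.

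Markers of other cell types moved in different directions. Of the Kupffer cell and macrophage markers 10 fell and 1 rose among 16, with a median of -1.11, and the list did not pass camera (adjusted p = 0.0902). The member that rose was Cd68, at 49.6 ± 9.98 against 2.36 ± 0.309 FPKM. Stellate cell and fibroblast markers rose in 10 and fell in 1 (Colec11) of 20 cases (camera adjusted p = 3.01e-05, and 0.199 with an estimated correlation). Krt8 and Krt18, keratins listed as cholangiocyte markers that hepatocytes also express, stood at 1067 ± 73.4 against 93.9 ± 16.4 and 1469 ± 167 against 172 ± 42.5 FPKM. Of the unfolded protein response genes 16 fell and 4 rose among 22 (camera adjusted p = 0.0908), with Herpud1 at -2.73. The 4 that rose were Ddit3, Trib3, Sesn2 and Ppp1r15a, genes induced downstream of ATF4.

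Camera called 21 of the 43 lists, and 2 of them held with an estimated correlation. Adjusted over the list alone, no count of any list moved by more than 2 genes. In total 1918 genes were higher and 4913 lower in WT than in Sham among 11728 tested (limma, adjusted p under 0.05). The median of all genes was -0.364, and with median-of-ratios scaling it was -0.026 and the split became 3169 higher and 3185 lower. Tnfrsf1a was lower in WT (-0.95, SE 0.185, adjusted p = 0.000749), but its fold change was 0.03 after quantile normalization.

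**Figure D1:**
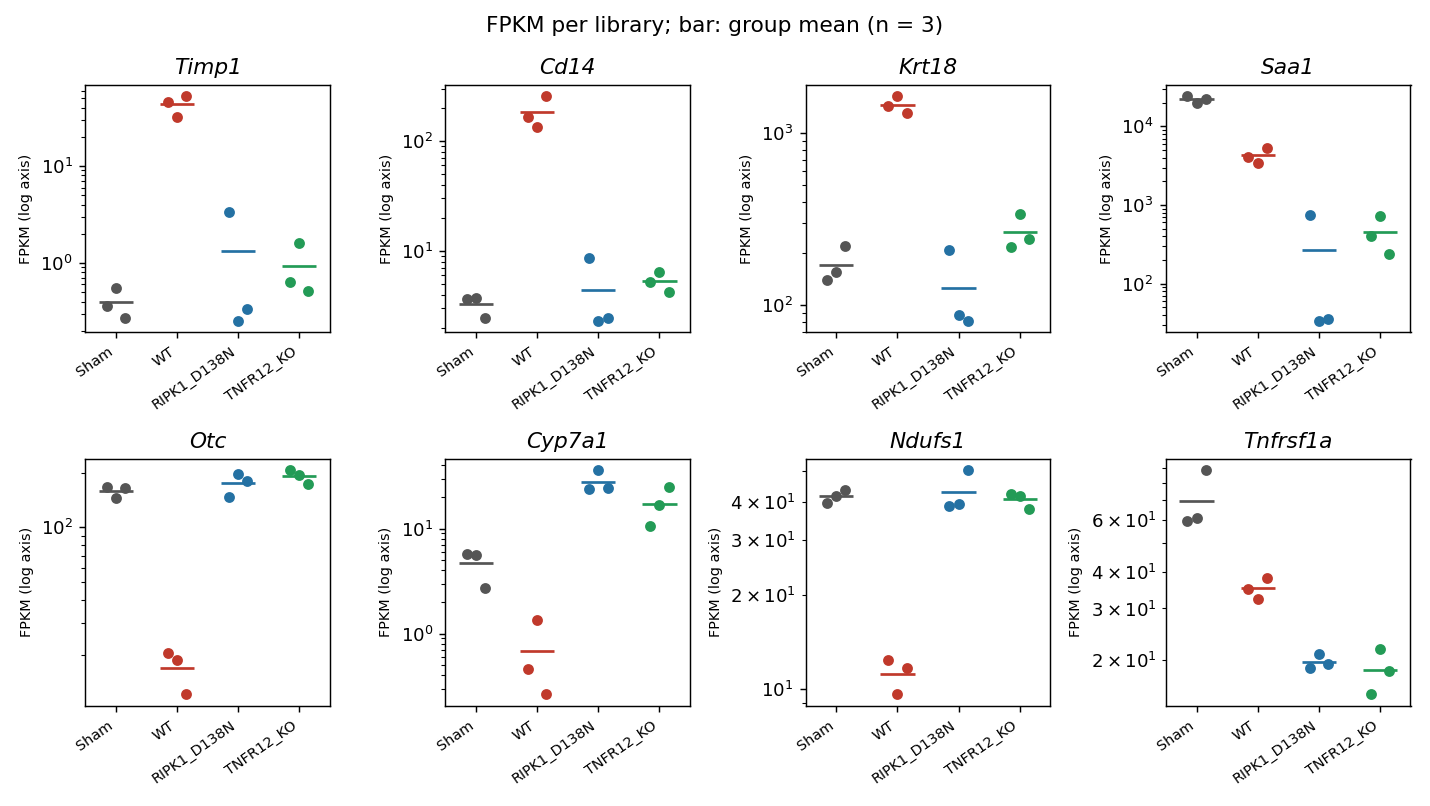
FPKM of 8 genes on log axes, with a point for each library and a bar for the mean of each group (n = 3). Cd14 averaged 185 FPKM in WT and 3.27 in Sham, 4.44 in RIPK1_D138N and 5.28 in TNFR12_KO, whereas Otc averaged 17.0 FPKM in WT and 158, 174 and 191 in Sham, RIPK1_D138N and TNFR12_KO.

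The comparison of RIPK1_D138N with WT asks how the kinase-dead genotype differs after ischemia. Cd14 stood at 4.44 ± 3.55 FPKM in RIPK1_D138N against 185 ± 62.8 in WT (log2 fold change -5.23, SE 0.359, limma adjusted p = 6.49e-07), and Lcn2, the acute-phase protein lipocalin 2, at 52.4 ± 61.3 against 2292 ± 454. Both read higher in replicate 1 than in the Xist-positive replicates 2 and 3, with Cd14 at 8.53 against 2.32 and 2.47 FPKM and Lcn2 at 122.7 against 24.6 and 9.86. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 28.1 ± 7.05 against 0.687 ± 0.572 FPKM (4.13, SE 0.332, adjusted p = 1.50e-06), and Slc10a1, the bile acid importer, at 283 ± 78.5 against 25.9 ± 9.45. Among the 6 largest rises were Hamp2, a hepcidin gene, and Cyp2b9, a cytochrome with female-biased expression, and both rose mainly in the Xist-positive libraries. The others, Cyp2a4, Cyp2c69, Cyp2c40 and Cyp4a14, also read far higher in replicates 2 and 3 than in replicate 1. Cyp2a4 read 7.38 FPKM in replicate 1 and 1347 and 1072 in replicates 2 and 3, and Cyp4a14 40.9 against 193 and 344. Hamp2 read 70.7 FPKM in replicate 1 and 2917 and 2883 in replicates 2 and 3, against 4.28 ± 0.866 in WT, and it no longer passed without the latter (log2 fold change 3.78, adjusted p = 0.0580). Cyp2b9 read 0.177 FPKM in replicate 1 and 146 and 129 in replicates 2 and 3.

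Hypoxia genes fell in 20 of 24 cases (camera adjusted p = 1.01e-09, and 0.00387 with an estimated correlation), including Aldoa, a glycolytic enzyme, at 55.4 ± 8.69 against 270 ± 14.2 FPKM. NF-κB targets fell in 11 and rose in 1 (Nfkbia) of 19 cases, with Relb at -2.04, and immediate early genes fell in 11 and rose in 1 (Fos) of 20 cases, with Klf6 at -2.58 and Myc at -1.88. Acute-phase genes fell in 18 of 27 cases, with Orm2 at -3.91, and 5 (Crp, Hp, Il6ra, Itih4 and Saa4) rose, of which Hp is listed at 0 in WT. All 31 oxidative phosphorylation genes rose (median 1.60), as did 22 of 26 secreted hepatocyte genes, 1 of them listed at 0 in a group. Periportal genes rose in 19 and fell in 2 (Apoa4 and Cdh1) of 22 cases, and pericentral genes rose in 20 and fell in 1 (Slc1a4) of 24. Among those that rose, Otc reached 174 ± 25.3 FPKM and F9 48.2 ± 3.92. Camera called these lists (adjusted p from 8.74e-12 to 0.00258). With an estimated correlation the adjusted p was 0.255 for NF-κB targets, 0.278 for both immediate early and acute-phase genes, 0.236 for oxidative phosphorylation and both zones, and 0.160 for secreted proteins. Tsc22d3, a glucocorticoid-induced gene, was higher at 103 ± 18.0 against 9.01 ± 0.613 FPKM, and Cd68 lower at 1.39 ± 0.314 against 49.6 ± 9.98. Camera called 22 of 43 lists, and 1 held with an estimated correlation. Adjusted over the list alone, no count moved by more than 4 genes. In all 3500 genes were higher and 2570 lower (limma). With median-of-ratios scaling these became 3122 and 3199, and the median of all genes 0.004 in place of 0.109. Both Xist-positive libraries were replicates of this group, and without the Xist-positive libraries 4335 were called in place of 6070. NF-κB targets then fell in 6 of 19 cases.

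The comparison of TNFR12_KO with WT asks the same of the libraries labelled TNFR1/2 knockout. Cd14 stood at 5.28 ± 1.06 FPKM against 185 ± 62.8 in WT (log2 fold change -4.85, SE 0.359, limma adjusted p = 9.89e-07), and Timp1 at 0.923 ± 0.611 against 43.4 ± 10.4. Cyp7a1 rose to 17.3 ± 7.12 FPKM (log2 fold change 3.42, SE 0.332, adjusted p = 5.50e-06) and Slc10a1 to 260 ± 34.7. Hist1h2al, a histone gene (ENSMUSG00000091383, chromosome 13, 51202727 to 51203065), stood at 59.6 ± 27.1 against 0.207 ± 0.197 FPKM.

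Hypoxia genes fell in 20 of 24 cases (camera adjusted p = 1.06e-11, and 0.00194 with an estimated correlation), and bile acid transport and synthesis genes rose in 18 of 23 (adjusted p = 1.91e-06, and 0.0324 with an estimated correlation). All 31 oxidative phosphorylation genes and all 26 secreted hepatocyte genes rose (medians 1.49 and 1.80, the latter with 1 member listed at 0 in a group). Complement and coagulation genes rose in 27 of 32 cases. Cytokines and chemokines fell in 12 and rose in 2 (Ccl5 and Cxcl9) of 21 cases, with Il1rn, the interleukin 1 receptor antagonist, at 1.80 ± 1.13 against 19.3 ± 5.88 FPKM. Camera called these lists (adjusted p from 1.06e-11 to 0.00594), and with an estimated correlation the adjusted p was 0.272, 0.130, 0.118 and 0.446. Immediate early genes fell in 7 and rose in 4 (Dusp1, Fos, Klf2 and Nr4a1) of 20 cases and did not pass camera (adjusted p = 0.138). Kupffer cell and macrophage markers fell in 8 and rose in 1 (Nr1h3) of 16 cases (adjusted p = 0.00594, and 0.298 with an estimated correlation), with C1qa at 3.91 ± 1.06 against 11.8 ± 2.61 FPKM. Camera called 23 of 43 lists, and 2 held with an estimated correlation. Adjusted over the list alone, no count moved by more than 2 genes. In all 3466 genes were higher and 2054 lower (limma). With median-of-ratios scaling these became 2903 and 2970, and the median of all genes -0.016 in place of 0.142.

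**Figure D2:**
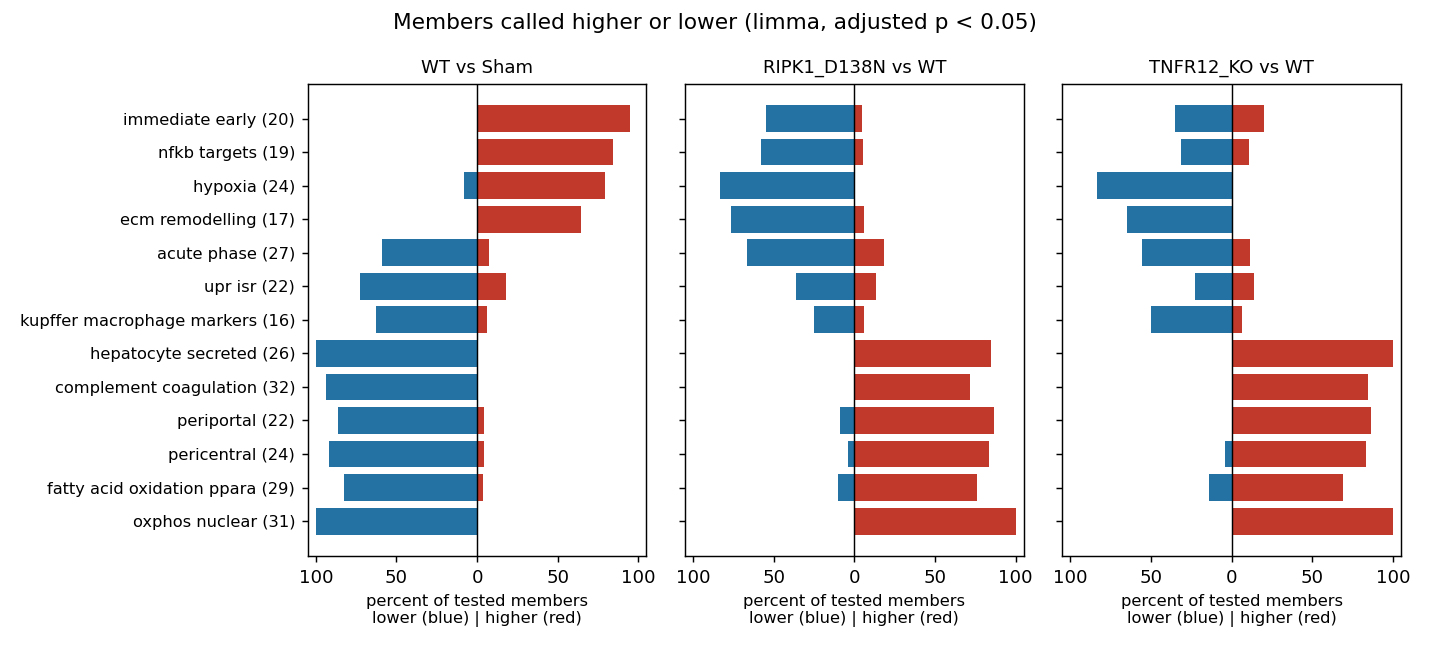
Percent of the tested members of 13 gene lists called higher (red, right) or lower (blue, left) by limma in 3 comparisons, with the number tested in parentheses. All 31 oxidative phosphorylation genes were lower in WT than in Sham and higher in both mutants than in WT. No trend on transcript length was removed for this list.

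The ischemia response score was 0.971 ± 0.062 in WT, 0.330 ± 0.022 in RIPK1_D138N, 0.342 ± 0.034 in TNFR12_KO and 0.038 ± 0.040 in Sham (mean ± SD, n = 3). Every library of either mutant lay below every WT and above every Sham library. The difference from WT was -0.641 for RIPK1_D138N and -0.629 for TNFR12_KO, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give (adjusted p = 0.125 over 5 comparisons). The mutants differed from each other by -0.011 (exact permutation p = 0.7). Of the 1918 genes higher in WT than in Sham, 1468 (76.5%) were lower in RIPK1_D138N than in WT and 1309 (68.2%) were lower in TNFR12_KO. Of the 4913 genes lower in WT, 2961 (60.3%) and 2954 (60.1%) were higher in the mutants. Independent lists would give 420 and 336 of the genes higher in WT and 1466 and 1452 of those lower, and regroupings that share the WT libraries gave at most 1. The regroupings hold no group difference, so such small counts follow from their construction and do not size the effect of shared libraries. The covariance of the WT vs Sham fold changes with those of RIPK1_D138N vs WT was -0.880 (regroupings: mean -0.0418, lowest -0.145), and with those of TNFR12_KO vs WT -0.844 (mean -0.0425, lowest -0.1415). The WT libraries are on both sides and too few to split, so part of these shares may come from them.

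**Figure D3:**
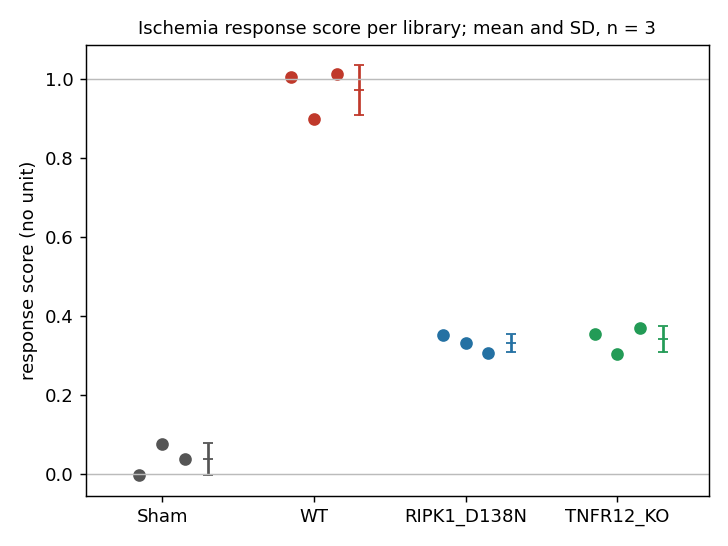
Ischemia response score of each library (no unit, 0 at Sham and 1 at WT), with the mean and SD of each group beside the points (n = 3). The 6 mutant libraries lay between 0.304 and 0.368, and the WT libraries between 0.899 and 1.012.

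Both mutants against WT shared 2966 higher and 1828 lower genes, and 7 were called in opposite directions. Independent lists of these sizes would share 1034 and 450, and random regroupings that share the WT libraries gave at most 1 in each direction. With no group difference in the regroupings, such small counts follow from their construction and do not size the effect of shared libraries. The covariance of the fold changes across genes was 0.892, against a mean of 0.0421 and a highest of 0.123 in the regroupings. With 3 WT libraries the controls could not be split with 2 on each side, so part of the overlap may come from the shared libraries.

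**Figure D4:**
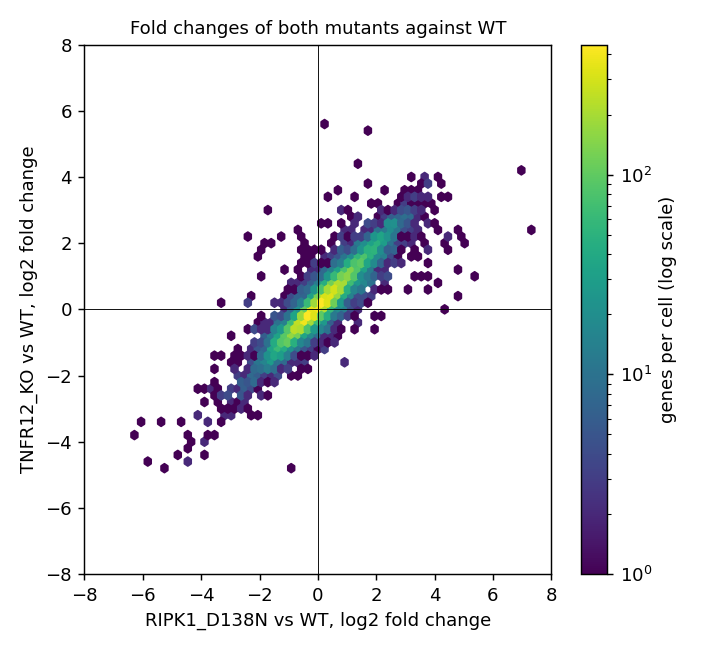
Log2 fold change against WT in RIPK1_D138N (horizontal) and TNFR12_KO (vertical) for 11704 genes, leaving out 24 listed at 0 in a group, with color giving the number of genes per cell on a log scale. Points run along the diagonal, with a correlation of 0.881 across all tested genes, which lies within the range of regroupings that share the WT libraries (mean 0.5005, highest 0.949).

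The direct comparison of RIPK1_D138N with TNFR12_KO called 41 genes higher and 68 lower (limma, adjusted p under 0.05, with 1444 at an unadjusted p under 0.05). Of these, 9 are in loci listed at 0 in either group and may be failed estimates. Without the loci listed at 0, 28 were higher and 50 lower. With median-of-ratios scaling the split was 44 higher and 40 lower. Hist1h2al stood at 0.552 ± 0.513 FPKM in RIPK1_D138N and 59.6 ± 27.1 in TNFR12_KO (log2 fold change -5.24, SE 0.341, adjusted p = 2.26e-06). Rps3a3, a ribosomal protein pseudogene relative that can share fragments with its parent, stood at 11.3 ± 1.60 against 104 ± 17.9, and Asic5, an ion channel gene, at 1.26 ± 0.351 against 16.0 ± 3.73. Rsad2 was lower in RIPK1_D138N at 2.45 ± 1.36 against 13.6 ± 1.97 FPKM. Nnmt was higher at 213 ± 65.8 against 44.0 ± 15.6 FPKM. Of the stellate cell and fibroblast markers 4 of 20 were higher and none lower (camera adjusted p = 1.21e-09, and 0.429 with an estimated correlation), or 9 adjusted over the list alone, with Ecm1 at 1.77, Lrat at 1.30, Rgs5 at 1.17 and Dcn, decorin, at 1.09. Camera called 13 of 43 lists, and 0 held with an estimated correlation. Adjusted over the list alone, no count moved by more than 11 genes. The count fell to 35 without the 2 Xist-positive libraries, to 27 without RIPK1_D138N replicate 3, to 32 without RIPK1_D138N replicate 2, to 29 and 47 without TNFR12_KO replicate 3 or 2 and to 59 without 1 WT library, which enters through the shared spread, and rose to 584 without RIPK1_D138N replicate 1. Without the Xist-positive libraries, which leaves 1 library of RIPK1_D138N, the log2 fold changes of Ecm1, Rgs5 and Dcn were 1.52, 1.11 and 1.12, and these were not called (adjusted p = 0.381, 0.429 and 0.385). The lone library is assumed to vary like the other groups.

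Against Sham, which differs from the mutants in genotype as well as operation, RIPK1_D138N had 881 genes higher and 2658 lower and TNFR12_KO 875 and 2127. With median-of-ratios scaling these became 1404 and 1235 for RIPK1_D138N and 1271 and 1095 for TNFR12_KO, and the medians of all genes went from -0.220 and -0.180 to 0.022 and 0.005. Immediate early genes rose in 15 of 20 cases in RIPK1_D138N and 18 of 20 in TNFR12_KO (camera adjusted p = 4.37e-18 and 1.82e-23, and 0.0564 and 0.0247 with an estimated correlation). Acute-phase genes fell in 19 and 21 of 27 cases with medians of -2.29 and -2.24 (camera adjusted p = 8.44e-08 and 1.54e-07, and 0.175 and 0.134 with an estimated correlation). The 2 members that rose, Hp and Serpina3m, are listed at 0 in Sham. Saa1, serum amyloid A, read 19790 to 24270 FPKM in Sham, 3416 to 5334 in WT and 236 to 725 in TNFR12_KO. In RIPK1_D138N it read 744 FPKM in replicate 1 and 33.8 and 36.0 in the Xist-positive replicates. Unfolded protein response genes fell in 16 of 22 cases in both mutants (camera adjusted p = 5.79e-06 and 3.62e-05, and 0.243 and 0.265 with an estimated correlation). None rose in RIPK1_D138N, and Ddit3 and Ppp1r15a, which are induced downstream of ATF4, rose in TNFR12_KO. Kupffer cell and macrophage markers fell in 10 and 12 of 16 (adjusted p = 8.97e-05 and 3.69e-07, and 0.175 and 0.110 with an estimated correlation). The oxidative stress list in RIPK1_D138N passed camera as higher (adjusted p = 0.0417, and 0.330 with an estimated correlation) with a median of 0.19 and a mean of -0.005. Camera called 26 and 24 of 43 lists, and 0 and 1 held with an estimated correlation. Adjusted over the list alone, no count moved by more than 4 and 3 genes. Secreted hepatocyte genes had medians of -0.24 and -0.11 and did not pass camera (adjusted p = 0.751 and 0.945). The 2 mutants shared 498 higher and 1729 lower genes against Sham, of which 250 and 1265 were called in the same direction in WT vs Sham as well. Independent lists would share 65.7 and 482, and random regroupings that share the Sham libraries gave 0 in each direction. Since no group differs in the regroupings, these counts follow from their construction and do not size the effect of shared libraries. Both comparisons use the same 3 Sham libraries, too few to split, so part of this overlap may come from them. Without the Xist-positive libraries the count for RIPK1_D138N was 1052 in place of 3539, without its replicate 3 it was 2245, and without TNFR12_KO replicate 3 that of TNFR12_KO was 1857 in place of 3002.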

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

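The tests of the 3 patterns weighed below were chosen after their results were seen, except the test of transcript length and the splits of the libraries. RIPK1_D138N and TNFR12_KO were tested against each other directly, and 109 genes differed between them (limma, adjusted p under 0.05, n = 3 per group). Of these, 9 are in loci listed at 0 in either group, and 78 genes were called without the loci listed at 0. The log2 fold changes of genes higher in RIPK1_D138N were 2.38 for Mme, 2.37 for Acot1, 2.28 for Nnmt, 2.21 for Cyp2c38, 2.05 for Ly6a, 2.00 for Gstt3, 1.77 for Ecm1, 1.17 for Rgs5 and 1.09 for Dcn. Those of genes lower in RIPK1_D138N were -5.24 for Hist1h2al, -3.88 for Mup9, -3.08 for Rps3a3, -2.91 for Asic5, -2.14 for Clec2h, -2.14 for Rsad2, -1.63 for Apoa4, -1.41 for Egfr, -1.41 for Plk2, -1.39 for Lrg1, -1.24 for Rnf43, -1.21 for Dbp and -1.01 for Cdh1. Mup9 can share fragments with Mup genes such as Mup10, Mup11, Mup19 and Mup20, which are listed at 0 in Sham and TNFR12_KO. It read highest in those same groups, at 301.5 to 874 FPKM in Sham and 114.6 to 192.5 in TNFR12_KO. Its difference may thus come from failed estimates of these genes, which was not tested. On leaving out each of the 12 libraries in turn, Mme, Acot1, Nnmt, Ly6a, Hist1h2al, Rps3a3, Asic5, Clec2h and Rsad2 kept their call throughout. Egfr, Lrg1 and Mup9 lost it in 11 cases, Cyp2c38 in 10, Gstt3 and Dbp in 9, Cdh1 in 6, and the others in 2 to 5. Clec2h lies within 10 Mb of the targeted Tnfrsf1a, so DNA carried along with that locus may account for its difference. Without both Xist-positive libraries only Nnmt, Hist1h2al, Rps3a3, Asic5 and Rsad2 of these genes were still called. The log2 fold change was then 0.79 for Cyp2c38, 0.95 for Gstt3, -1.21 (-1.209) for Mup9, -0.56 for Egfr and -0.63 for Lrg1. Other genes lost their call with a fold change about as large, among them Acot1 at 2.43 (adjusted p = 0.0505), Dbp at -1.23, Cdh1 at -1.135, Rgs5 at 1.11 and Dcn at 1.12. That fit holds 1 RIPK1_D138N library, so these losses do not show that a difference depends on the Xist-positive ones. The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For this comparison 1 split, the real one, gave as many genes, and the highest of the others gave 18. The real and the highest other counts were 6831 and 0 for WT vs Sham, 6070 and 1 for RIPK1_D138N vs WT, 5520 and 1 for TNFR12_KO vs WT, 3539 and 2 for RIPK1_D138N vs Sham, and 3002 and 1 for TNFR12_KO vs Sham.

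Gene lists that differed between the mutants (camera, adjusted p under 0.05) had these median log2 fold changes in RIPK1_D138N against TNFR12_KO. Immediate early genes stood at -0.62, NF-κB targets at -0.49 and circadian genes at -0.29. Platelet markers stood at 1.21, stellate cell markers at 0.71 (0.705), endothelial markers at 0.68, heat shock genes at 0.46, lymphocyte markers at 0.42, Kupffer cell markers at 0.31, pericentral genes at 0.28, ribosomal protein genes at 0.20, fatty acid oxidation genes at 0.12 (0.115) and oxidative phosphorylation genes at 0.09 (0.087). None passed with an estimated correlation. On leaving out 1 library, pericentral (lowest median 0.098), platelet (0.293), circadian, fatty acid oxidation (-0.001), oxidative phosphorylation (-0.051) and ribosomal protein genes (0.007) no longer passed camera in at least 1 case. The endothelial median fell to 0.270 but still passed. Without the Xist-positive libraries the lists that no longer passed were NF-κB targets (median -0.128, adjusted p = 0.706), lymphocyte markers (-0.068, adjusted p = 0.643), endothelial markers (-0.442, adjusted p = 0.375), fatty acid oxidation (0.033, adjusted p = 0.102), and heat shock, Kupffer cell and oxidative phosphorylation genes (0.172, 0.164 and 0.085, each with an adjusted p of 0.0536). The stellate median was then 0.298 with 0 members called, and the list passed (adjusted p = 0.00207).

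RIPK1_D138N replicates 2 and 3 stood apart from replicate 1. A difference of sex may account for this. Of 26 genes with sex-biased expression that were listed beforehand and reached 1 FPKM, 25 (96.2%) differed in the direction of female minus male in both libraries. The 26 genes include Xist and the Y-linked Ddx3y, Eif2s3y and Uty, so the count is not independent of the Xist and Ddx3y values already seen. In the other groups of the series 0 libraries held Xist at 1 FPKM or more. This cannot exclude a swap with another group, since the Xist-positive libraries could have come from there and left none behind. A swap with another group or an outside sample and animals of both sexes within the group stay open. The sex-biased genes were used to look for the difference after Xist had been seen, so this remains a hypothesis.

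Acute-phase genes were lower in both mutants than in Sham. A smaller share of hepatocyte RNA would lower other hepatocyte products alike. However, the secreted hepatocyte median in TNFR12_KO vs Sham was -0.109 (bootstrap SE 0.071, from resampling the genes of the list, not libraries). Median-of-ratios scaling did not remove the fall in TNFR12_KO vs Sham, where the acute-phase median was then -1.998 (bootstrap SE 0.248). The sex of the RIPK1_D138N animals cannot account for the fall in TNFR12_KO, which had no Xist-positive library and a median of -2.235 (bootstrap SE 0.249). In RIPK1_D138N without its Xist-positive libraries, which leaves only replicate 1, the median against Sham was -2.143. Whether sex adds to the fall in the Xist-positive libraries was not tested. With the loci listed at 0 left out, 16 of 25 acute-phase genes also fell in WT vs Sham and 1 rose (median -1.318). Both of those groups are wild type, so a fall of this list did not need a mutant genotype. Without those loci the medians against Sham were -2.363 in RIPK1_D138N and -2.374 in TNFR12_KO. What genotype, operation and handling each add in the mutants cannot be told apart, because 0 Sham libraries are of a mutant genotype.

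Hepatocyte transcripts were lower in WT than in Sham. With median-of-ratios scaling the secreted hepatocyte median was -1.570 (bootstrap SE 0.191), and after removal of the trend on transcript length it was -1.958 (SE 0.236), so neither removed the fall. That scaling takes most genes as unchanged, while 6831 of 11728 were called here. The FPKM totals were 649373 to 750501 in Sham and 288934 to 303514 in WT. Scaling to equal totals would make the fall smaller and was not tested. A smaller share of hepatocytes alone would raise the markers of every other cell type, but the Kupffer marker median lay at -0.747 (SE 0.289) from that of all genes and the stellate median at 1.074 (SE 0.253). All these SEs resample the genes of a list, not libraries, so they hold no spread between libraries. The Kupffer list also did not pass camera in this comparison, so these values do not settle the question. A fall in both hepatocyte and Kupffer cell RNA, and a lower transcript level per hepatocyte, stay open.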

How the results depend on the processing

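The fits without the Xist-positive libraries and without loci listed at 0 were chosen after the data were seen. WT vs Sham and both comparisons of a mutant with WT stayed within 1.5 times their total counts under every alternative, as did the overlap of the mutants. Leaving out 1 library at a time moved these totals to 5782 to 7000, 4759 to 6286, 4315 to 5766 and 3693 to 4990. The split by direction was less stable. WT vs Sham went from 1918 higher and 4913 lower to 3169 and 3185 with median-of-ratios scaling. That scaling kept 5103 of its 6831 calls in the same direction, and quantile normalization kept 5024. In RIPK1_D138N vs WT they kept 5688 and 5377 of 6070, and in TNFR12_KO vs WT 4957 and 4833 of 5520. RIPK1_D138N vs TNFR12_KO did not hold its count of 109: it was 60 with no filter on low values, 20 in a fit of only the groups compared, 1789 with array weights, 35 without the Xist-positive libraries, and 27 (without RIPK1_D138N replicate 3) to 584 (without RIPK1_D138N replicate 1) on leaving out 1 library. Without the loci listed at 0 the count was 78 (28 higher and 50 lower). The fit of fewer libraries has fewer degrees of freedom, and otherwise the cause was not tested. RIPK1_D138N vs Sham gave 6030 with array weights, 1052 without the Xist-positive libraries and 2245 to 3778 on leaving out 1 library, and TNFR12_KO vs Sham 1857 to 3260; the cause was not tested. The response score difference of RIPK1_D138N from WT was -0.691 after quantile normalization and -0.673 to -0.588 on leaving out 1 library, and that of TNFR12_KO -0.657 to -0.580. Replicate numbers did not pair RIPK1_D138N with TNFR12_KO: the correlations of the 3 pairs were -0.097, -0.202 and 0.057, and 1 of the 6 samples correlated best with its own number. With the replicate block this comparison called 113 genes, 60 higher and 53 lower, and 81 of the 109 kept their call and direction. No paired analysis was possible for the other comparisons because the numbers of the WT and Sham columns could not each be matched to a single sample.

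Across all genes called, quantile normalization gave the opposite call for 79 of 6831 in WT vs Sham, 7 in RIPK1_D138N vs WT and 1 in TNFR12_KO vs WT, and the fit without the Xist-positive libraries for 1 in RIPK1_D138N vs WT. Among named genes and lists, values that changed sign were all from tests that had not passed, except Tnfrsf1a in WT vs Sham, which was 0.031 after quantile normalization, and 4 list medians in RIPK1_D138N vs TNFR12_KO; the cause was not tested. Without the Xist-positive libraries the endothelial median was -0.442 and the lymphocyte median -0.068, and without TNFR12_KO replicate 3 that of oxidative phosphorylation was -0.051 and that of fatty acid oxidation -0.001. These lists no longer passed camera, and its direction changed for the endothelial one. Ripk1 in TNFR12_KO vs WT was -0.136 with median-of-ratios scaling, -0.021 after quantile normalization, -0.125 with array weights, and from -0.122 to 0.128 on leaving out 1 library, with -0.004 without TNFR12_KO replicate 3. In RIPK1_D138N vs TNFR12_KO, Tnfrsf1a ranged from -0.022 to 0.221 and Tnfrsf1b from -0.50 to 0.028 on leaving out 1 library. Of the values of named genes, 18 lost their call without the Xist-positive libraries, 16 in a fit of only the groups compared and 12 with no filter. The first of these fits holds 1 RIPK1_D138N library, and some fold changes in it stayed about as large, such as 2.43 for Acot1 and 1.12 for Dcn in RIPK1_D138N vs TNFR12_KO. Depth limits low genes most in 2 of the 3 Sham libraries, with 11.4 fragments behind 1 FPKM per kilobase.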

Other observations

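The tests of DNA near the targeted genes were chosen after the data had been seen. Erythroid transcripts were higher in both mutants than in WT. Of 9 tested erythroid genes 7 were higher in RIPK1_D138N (camera adjusted p = 0.00157, and 0.228 with an estimated correlation) and 8 in TNFR12_KO (adjusted p = 0.000444, and 0.168 with an estimated correlation). Hbb-bs, a beta-globin gene, stood at 779 ± 403 FPKM in RIPK1_D138N against 54.2 ± 20.1 in WT, and Hbb-bt at 77.3 ± 31.8 in TNFR12_KO against 4.23 ± 2.25 (mean ± SD, n = 3). Lipogenic genes were higher in 14 of 19 cases and lower in 1 (Insig2) in both mutants (camera adjusted p = 0.00157 and 0.00225, and 0.498 and 0.522 with an estimated correlation). Without the Xist-positive libraries 8 of 19 were higher in RIPK1_D138N, with a median log2 fold change of 0.76 (0.762) in place of 1.94 (camera adjusted p = 0.0467). Dbp, an output gene of the circadian clock, stood at 110 ± 7.79 FPKM in TNFR12_KO, 46.9 ± 5.399 in RIPK1_D138N and 11 ± 5.52 in WT.

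Moxd1, a monooxygenase gene singled out after its values were seen, read 30.0 to 49.7 FPKM in Sham and at most 0.490 FPKM in each of the other 9 libraries, whichever genotype they were labelled with.

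A knockout line can carry strain DNA around the targeted gene, which may change nearby transcripts. Genes called between the mutants made up 2.05% of those within 10 Mb of Tnfrsf1a or Tnfrsf1b (6 of 292) and 0.9% elsewhere (103 of 11436), a ratio of 2.28 (Fisher's exact test across genes, two-sided, p = 0.0547, adjusted p = 0.109). The 6 genes were Fam213b, Clec2h, Plekhg6, Iffo2, Klhdc7a and Gm7298. Near Ripk1 the ratio was 1.64, from 1 of 66 genes, Foxq1 (Fisher's exact test, two-sided, p = 0.461, adjusted p = 0.461). The counts are too small to decide, and genes are not independent replicates.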
